A study of Homo sapiens with 4 samples.

How the data were processed

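The series measured messenger RNA in 2 human epithelial cancer cell lines, each kept in 2 culture media. H441 is a line from a lung adenocarcinoma and HT29 a line from a colorectal adenocarcinoma. Per the labels, cells were cultured for 7 days in RPMI-1640, a conventional medium, or in HPLM, a medium made up to hold amino acids, glucose and other small molecules near their levels in human plasma, both with 10% fetal bovine serum. Poly(A) RNA was extracted with Qiagen RNeasy columns and made into libraries with the Illumina TruSeq RNA Library Prep Kit v2, per the labels' protocols. That kit keeps no record of strand, so reads of a gene and of an antisense or overlapping gene cannot be told apart. GEO lists 4 samples, 1 per line and medium, while the deposited tables hold 3 numbered columns for each of them, 12 in all, which are called libraries here. The labels do not say whether these libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

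Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.2, DESeq2 and the genome build GRCh38 were used. The version of DESeq2, the role and order of the tools and the gene annotation are not given in the sources used here. For each line the authors deposited TPM values of 58051 gene identifiers in 6 libraries. A second deposited table per line gives the authors' log2 fold change of HPLM over RPMI-1640, with the authors' p-value and adjusted p-value, for 15405 genes in H441 and 16126 in HT29. The same table holds the deposited signal per library, which is a read count per gene divided by a size factor. Multiplying that signal by a size factor, found from the gaps between its small values and refined by least squares, gave whole reads, a recovered count per gene: 100% of values in all 12 libraries lay within 0.01 of a read of a whole number, and the smallest value was 1 read except in H441 HPLM library 3, where it was 2 reads. The sign of the authors' fold change matched that of the deposited signal, as HPLM over RPMI-1640, in 99.4% of genes in H441 and 99.4% in HT29. Symbols and coordinates came from a GRCh38 gene annotation, which gave a symbol to 56948 identifiers.

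The tests, the gene lists, the rule for named genes and the alternatives below were chosen before the data were examined, except where stated. Each line was fitted alone with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options) on log2(TPM + 1), for genes with a TPM of at least 1 in at least 3 libraries. A fit that left out a library asked only for as many libraries as the smaller medium group had, a looser filter. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and the threshold was 0.05. Fold changes are on the log2(TPM + 1) scale, HPLM over RPMI-1640, and understate the change of genes with low TPM. Errors of log2 fold changes are standard errors and errors of TPM are SD over 3 libraries. The difference between lines was an interaction term over all 12 libraries, HT29 minus H441. It took a shared variance per gene for both lines, although the HT29 RPMI-1640 libraries spread more, so its p-values can be too small. Overlap of calls was tested with Fisher's exact test. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of 1 comparison. Camera compares a list with the other genes, while fry asks whether its members move on balance 1 way. Of 44 lists fixed in advance, 20 are described for both lines, and of the rest those that camera called are given among the other observations. Markers of fibroblasts, leukocytes and endothelial cells were looked at as levels.

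Named genes were taken by rule. Per line these were the 10 genes raised most and the 10 lowered most past the threshold, with a mean TPM of at least 5, the same direction in the authors' deposited table and no clone-type symbol; the 2 members of each described list with the smallest adjusted p and a mean TPM of at least 1; and, whatever their values, ASNS, TRIB3, CHAC1, DDIT4, PHGDH, PSAT1, SLC7A11, SLC7A5, MAT2A, ASS1, TXNIP, HMGCS1, CAV1 and CLTC. For the difference between lines the 5 genes with the largest difference in each direction were taken, with a mean TPM of at least 5 in both lines. A pair of genes that the rule names is not reported here, as was asked from outside the analysis. Genes outside this rule, such as members that went against their list, were named after their values were seen.

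Recovered reads numbered 14.2 to 30.6 M per library. Data were simulated with 200 changed genes and, in every library, the same spread per gene, estimated from the libraries of the fit. In H441 limma recovered 66.3% of genes changed 1.5-fold and 83.0% of those changed 2-fold, over 14303 genes. In HT29 it recovered 0% at either size with all libraries (14643 genes), and 38.0% and 84.4% without RPMI-1640 library 1 (14749 genes). For the difference between lines the shares were 4.82% and 20.4%, over 13571 genes. With all HT29 libraries, the spread added by RPMI-1640 library 1 was thus drawn into every simulated HT29 library. The HT29 shares with all libraries and those of the difference therefore do not give the power in the real data. The H441 shares also rest on 200 changed genes, while limma called 7404 in the real data. The Benjamini-Hochberg cutoff is stricter when fewer genes change, so these shares may understate the power in H441.

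TPM of all genes sum to the same total in every library, so a change in a few abundant transcripts shifts all others. Rescaling by the trimmed mean of M-values moved the median log2 fold change of all genes from 0.14 to 0.02 in H441 and from -0.07 to 0.02 in HT29. Alternatives were other pseudocounts and TPM filters, TPM without mitochondrially encoded genes, median centring, trimmed mean scaling, an intensity trend, a replicate block, leaving out each library, stricter thresholds and the authors' own tests. Added after the data were seen were edgeR 4.0.16 (quasi-likelihood test) on the recovered reads, array weights, the set of genes in the authors' table, gene lists and overlaps without HT29 RPMI-1640 library 1, and scaling alternatives for the lists, the overlap and the difference. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes with near-identical copies, among them HSPA1A and HSPA1B, AKR1C1, AKR1C2 and AKR1C3, SFTPA1 and SFTPA2, SPRR2D, PRSS2, ANKRD36C, FRG2EP, NMRAL2P, IGFL1P1 and IGLV2-14, may share reads, and their values are uncertain.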

Results

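Poly(A) RNA of H441 and HT29 cells was sequenced after 7 days in RPMI-1640 or HPLM, with 3 libraries per line and medium and 14.2 to 30.6 M recovered reads in each. The title of the series concerns amino acids and the delivery of mRNA in lipid nanoparticles. The comparison asks how the transcriptome of each line differed between a conventional and a plasma-like medium. Both lines carried the transcripts of their tissue of origin. NKX2-1, a transcription factor of lung epithelium, stood at 174 ± 0.109 TPM (SD, n = 3) in H441 and 0.481 ± 0.320 TPM in HT29 in RPMI-1640, and KRT20, an intestinal keratin, at 2.21 ± 1.11 and 1081 ± 366 TPM. Of markers of other cell types, 9 of 13 fibroblast, 6 of 9 endothelial and 2 of 14 leukocyte genes never reached 1 TPM. Those above included COL1A1, a fibrillar collagen, at 35.7 ± 2.46 TPM and KDR, a VEGF receptor, at 20.2 ± 0.239 TPM in H441 in RPMI-1640, and LYZ, which encodes lysozyme, at 2929 ± 1255 TPM in HT29 in RPMI-1640. Some leukocyte markers were present at low levels in both lines. In RPMI-1640, CD3D stood at 7.11 ± 1.34 TPM in H441 and 6.29 ± 4.43 TPM in HT29. The source of these reads was not tested.

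Libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom of 1.88 to 6.90 in H441 and 3.15 to 15.4 among the HPLM libraries of HT29. HT29 RPMI-1640 library 1, which has the fewest reads, stood apart: its ratio was 203 against library 2 and 258 against library 3, while libraries 2 and 3 gave 13.3. Most HT29 changes are therefore given with all libraries and again without it. Differences of single genes between the lines are given with all libraries unless stated. Mitochondrially encoded genes took 26.3% ± 2.38 of TPM in H441 in RPMI-1640 and 19.0% ± 2.29 in HPLM. In HT29 their share was 26.1% ± 5.95 in RPMI-1640, with 19.3% in library 1, and 33.8% ± 4.56 in HPLM.

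In H441, HPLM raised 27 of 33 ATF4 targets, 19 of 20 unfolded protein response genes and 10 of 14 heat shock genes. It lowered 13 of 24 sterol genes and 26 of 28 cell cycle genes, and TXNIP and ARRDC4. Camera called these 5 lists with its preset correlation and none with an estimated one. TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600), which encodes a thioredoxin-binding protein that limits glucose uptake, fell to 49.4 ± 1.78 TPM in HPLM against 1196 ± 52.2 TPM in RPMI-1640, a log2 change of -4.57 ± 0.06 (adjusted p = 1.07e-05, limma with Benjamini-Hochberg adjustment). HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214), the inducible heme oxygenase, rose to 572 ± 18.1 TPM in HPLM against 38.4 ± 2.23 TPM in RPMI-1640, a log2 change of 3.86 ± 0.06 (adjusted p = 1.45e-05). DDIT3 (ENSG00000175197, chromosome 12, 57516588 to 57521737), which encodes the stress factor CHOP, rose to 1037 ± 26.5 TPM in HPLM against 111 ± 2.28 TPM in RPMI-1640. ATF3 (ENSG00000162772, chromosome 1, 212565334 to 212620777), a related stress-induced transcription factor, rose by 3.29 ± 0.06. INSIG1 (ENSG00000186480, chromosome 7, 155297776 to 155310235), which holds the sterol regulator SREBP in the endoplasmic reticulum, fell to 24.6 ± 0.742 TPM in HPLM against 86.7 ± 1.46 TPM in RPMI-1640.

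**Figure D1:**
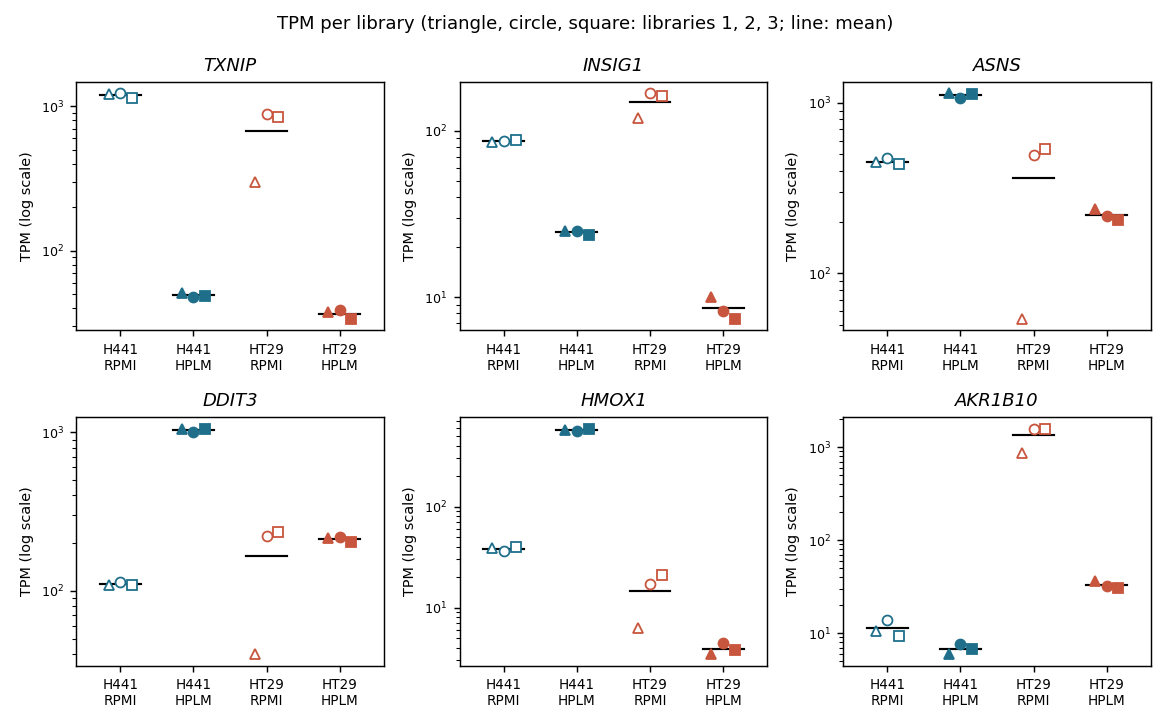
TPM of TXNIP, INSIG1, ASNS, DDIT3, HMOX1 and AKR1B10 in each library on a log axis, with RPMI-1640 open, HPLM filled, triangles, circles and squares for libraries 1, 2 and 3, and a line at the mean of each group. ASNS in HT29 stood at 54.0 TPM in RPMI-1640 library 1 and at 494 and 537 TPM in libraries 2 and 3.

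Of 33 tested targets of ATF4, the transcription factor of the amino acid response, 27 rose and 1 fell in H441, and adjusted over the list alone 27 rose and 1 fell. The list's median log2 change was 0.96 (camera adjusted p = 1.55e-09, and adjusted p = 0.593 with an estimated correlation). ASNS, which makes asparagine, rose by 1.30 ± 0.06 on the log2 scale to 1115 ± 39.0 TPM in HPLM against 452 ± 19.0 TPM in RPMI-1640. TRIB3, a pseudokinase induced by stress, rose by 1.84 ± 0.06. CHAC1, which degrades glutathione, rose by 1.68 ± 0.08, and DDIT4, an inhibitor of mTORC1, by 0.96 ± 0.06. PSAT1, of serine synthesis, rose by 0.92 ± 0.06. The cystine transporter SLC7A11 rose by 0.75 ± 0.06 and the leucine transporter SLC7A5 by 0.71 ± 0.07 (adjusted p at most 9.74e-04 for these 7). ALDH18A1, of proline synthesis, was the member that fell (-0.24). PHGDH, the first enzyme of serine synthesis, stood at 1.05 ± 0.168 TPM in HPLM with a log2 change of -0.02 ± 0.14 (adjusted p = 0.914). Its sign was positive without RPMI-1640 library 2 (0.12) or HPLM library 3 (0.04). PPP1R15A, whose product directs dephosphorylation of eIF2alpha, rose to 300.2 ± 7.80 TPM in HPLM against 43.7 ± 3.76 TPM in RPMI-1640. Of the 23 cytosolic aminoacyl-tRNA synthetases and their cofactors, which charge tRNAs, 17 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 3.27e-04, and adjusted p = 0.684 with an estimated correlation). AARS1 rose by 1.04 ± 0.06 and TARS1 by 0.96 ± 0.05, the synthetases for alanine and threonine, while QARS1, for glutamine, fell (-0.28). Among 18 plasma membrane amino acid transporters 11 rose and 2 fell (12 and 2 adjusted over the list alone). Camera did not call the list (median 0.34, adjusted p = 0.0929). It did after trimmed mean scaling (median 0.22, adjusted p = 0.0281, and adjusted p = 0.298 with an estimated correlation). SLC1A4, a transporter of neutral amino acids, rose by 1.84 ± 0.08. SLC6A6 and SLC6A8, for taurine and creatine, both fell, with log2 changes of -1.05 and -0.59.

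Of 20 genes of the unfolded protein response, 19 rose and 0 fell, the same numbers adjusted over the list alone, with a median of 1.24 (camera adjusted p = 1.55e-09, and adjusted p = 0.593 with an estimated correlation). DNAJB9, a cochaperone of the endoplasmic reticulum, rose by 2.83 ± 0.07, and HERPUD1, of the degradation pathway there, rose by 2.27 ± 0.05. Heat shock genes rose in 10 of 14 cases and fell in 1 (10 and 1 adjusted over the list alone), the exception being HSPB1, a small heat shock protein, at -0.35. Their median was 0.43 (camera adjusted p = 0.00529, and adjusted p = 0.622 with an estimated correlation). HSPA6, an inducible HSP70, rose to 89.5 ± 3.62 TPM in HPLM against 7.08 ± 0.585 TPM in RPMI-1640; HSPA1A and HSPA1B, inducible HSP70 genes of near-identical sequence, rose by 2.81 ± 0.09 and 2.46 ± 0.06. Of 17 immediate early genes, which respond within minutes to stimuli, 15 rose and 0 fell (16 and 1 adjusted over the list alone), with a median of 0.86 (camera adjusted p = 4.91e-06, and adjusted p = 0.593 with an estimated correlation). EGR1, a zinc finger factor, rose by 2.44 ± 0.06 and MYC by 1.68 ± 0.05. Other genes raised most were HBEGF, a ligand of the EGF receptor (2.86 ± 0.06), MMP9, a gelatinase (2.90 ± 0.15), and SPRR2D, of the cornified envelope (3.05 ± 0.15).

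Glucose-sensing genes downstream of MondoA and ChREBP were lowered at TXNIP and at its relative ARRDC4, which fell to 5.42 ± 0.446 TPM in HPLM against 44.4 ± 2.16 TPM in RPMI-1640 (-2.82 ± 0.07). Of 6 members 2 rose and 3 fell, the same numbers adjusted over the list alone. Camera did not call the list (median -0.23, adjusted p = 0.0793). Of 24 genes of cholesterol synthesis and SREBP2, 13 fell and 2 rose, the same numbers adjusted over the list alone, with a median of -0.23 (camera adjusted p = 1.32e-06, and adjusted p = 0.593 with an estimated correlation). INSIG1 changed by -1.78 ± 0.05 and HMGCS1, of the mevalonate pathway, by -0.23 ± 0.06 (adjusted p at most 0.0261). FDFT1, which makes squalene, fell to 32.4 ± 1.02 TPM in HPLM against 65.6 ± 2.49 TPM in RPMI-1640. The HMGCS1 call was lost on leaving out any 1 library but HPLM library 1, with log2 changes of -0.28 to -0.20 over the 6 omissions (adjusted p = 0.0314 to 0.0834). Fatty acid synthesis genes fell in 7 of 17 cases and rose in 1 (9 and 1 adjusted over the list alone; median -0.19, camera adjusted p = 4.91e-06, and adjusted p = 0.593 with an estimated correlation). SCD, the stearoyl-CoA desaturase, fell to 50.9 ± 1.08 TPM in HPLM against 172 ± 12.3 TPM in RPMI-1640, and ACSS2, which makes acetyl-CoA from acetate, changed by -1.39 ± 0.05. In glycolysis and glucose uptake 13 of 24 genes fell and 5 rose (14 and 6 adjusted over the list alone). The median of -0.22 and the camera test (down, adjusted p = 0.00160, and adjusted p = 0.708 with an estimated correlation) lay below 0, and the mean of 0.01 did not. The lactate transporter SLC16A1 rose by 2.11 ± 0.07 and hexokinase HK2 by 1.05 ± 0.07.

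NRF2 targets and glutathione genes moved both ways in H441: 15 of 22 fell and 6 rose (16 and 6 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 1.75e-05, and adjusted p = 0.593 with an estimated correlation). AKR1C1 and AKR1C3, aldo-keto reductases, both fell, with log2 changes of -2.29 and -2.20. The raised members were HMOX1, OSGIN1 (1.48), SLC7A11, GCLM (0.71), SRXN1 (0.51) and the ferritin gene FTH1 (0.23). Cell cycle and DNA replication genes fell in 26 of 28 cases, 27 adjusted over the list alone, with a median of -0.50 (camera adjusted p = 1.37e-17, and adjusted p = 0.593 with an estimated correlation). MKI67, the proliferation marker, changed by -0.79 ± 0.06 and cyclin A2, CCNA2, by -0.69 ± 0.05; CDC6, which loads the replicative helicase, rose (0.61). Mitochondrially encoded mRNAs fell in 12 of 13 cases, the same number adjusted over the list alone (median -0.49, camera adjusted p = 4.47e-07, and adjusted p = 0.593 with an estimated correlation), with MT-ND6 at -0.94 ± 0.12 and MT-ND5 at -0.82 ± 0.11. Cytosolic ribosomal protein genes rose in 21 of 25 cases, the same number adjusted over the list alone (median 0.31, camera adjusted p = 0.00107, and adjusted p = 0.708 with an estimated correlation), and in 10 after trimmed mean scaling (median 0.16). RPL3, of the large subunit, rose by 0.31 ± 0.04.

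Lung epithelial genes fell in 4 of 11 cases and rose in 2 (5 and 2 adjusted over the list alone; median -0.18, camera adjusted p = 0.00497, and adjusted p = 0.593 with an estimated correlation). The surfactant protein genes SFTPA1 and SFTPA2 changed by -1.70 ± 0.05 and -1.69 ± 0.05, SFTPA1 from 1452 ± 24.7 to 447 ± 12.0 TPM. Of 7 colonic epithelial genes 2 rose and 2 fell, the same numbers adjusted over the list alone (median -0.19, camera adjusted p = 0.107). The cell surface glycoprotein genes CEACAM5 and CEACAM6 changed by -2.30 ± 0.05 and -1.23 ± 0.08. Interferon response genes fell in 8 and rose in 4 of 26 cases, the same numbers adjusted over the list alone (median -0.10, camera down, adjusted p = 0.00529, and adjusted p = 0.630 with an estimated correlation), with the antiviral sensor OAS1 at -0.83 ± 0.06 and the transcription factor IRF1 at 1.12 ± 0.09. Hypoxia genes rose in 5 and fell in 8 of 22 cases (9 and 8 adjusted over the list alone). Their median was 0.11, and -0.03 after trimmed mean scaling, with a mean of 0.07 and a camera direction of down (adjusted p = 0.243). VEGFA, the angiogenic factor, rose by 1.47 ± 0.05, and PPFIA4, a liprin, changed by -0.69 ± 0.05. Among clathrin-mediated endocytosis genes 4 of 22 rose and 2 fell, the same numbers adjusted over the list alone. Their median of 0.02 and mean of 0.01 lay above 0 and the camera direction was down (adjusted p = 0.212); after trimmed mean scaling the median was -0.12 (adjusted p = 0.0282, and adjusted p = 0.323 with an estimated correlation). PICALM, a clathrin adaptor, rose by 0.31 ± 0.05 and the sorting nexin SNX9 by 0.39 ± 0.06, and after trimmed mean scaling by 0.17 and 0.25. The clathrin heavy chain gene CLTC did not pass the test (-0.18 ± 0.07, adjusted p = 0.0776) but fell after trimmed mean scaling (-0.32, adjusted p = 0.00354). Of 9 caveolae genes 5 rose and 0 fell, the same numbers adjusted over the list alone. The median of 0.16 was not called (camera adjusted p = 0.140) and was -0.02 after median centring. Caveolin CAV1 rose by 0.62 ± 0.05 and CAVIN2, of the caveolar coat, by 1.08 ± 0.07. MAT2A, which makes S-adenosylmethionine, changed by -0.27 ± 0.05 (adjusted p = 0.00652). ASS1, of arginine synthesis, changed by -0.13 ± 0.09 (adjusted p = 0.298). Other genes lowered most were FRG2EP, a pseudogene (-2.87 ± 0.15), CLDN8, a claudin of tight junctions (-2.32 ± 0.09), RNASE1, a secreted ribonuclease (-1.87 ± 0.05), and ANKRD36C, of a family of near-identical ankyrin repeat genes (-1.71 ± 0.07).

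In all, limma called 7404 of 16458 genes in H441, 5546 raised and 1858 lowered, of which 482 and 108 changed 2-fold or more. The split depended on scaling: it was 4004 raised and 3355 lowered without mitochondrially encoded genes, 3873 and 3497 after trimmed mean scaling, 3208 and 4171 after median centring, 4381 and 4190 by edgeR on recovered reads, and 3662 and 3775 in the authors' deposited table. Without RPMI-1640 library 1 the lowered genes numbered 1233. The lists camera called in H441, 19 of 43, numbered 0 with an estimated correlation and 30 by fry.

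In HT29, HPLM lowered 16 of 23 NRF2 targets, 11 of 24 sterol genes, 3 of 7 glucose-sensing genes and 13 of 28 cell cycle genes. Camera called these lists with its preset correlation and none with an estimated one. AKR1B10 (ENSG00000198074, chromosome 7, 134527592 to 134541408), an aldo-keto reductase, fell to 33.1 ± 3.27 TPM in HPLM against 1339 ± 407 TPM in RPMI-1640, a log2 change of -5.25 ± 0.27 (adjusted p = 0.00289, limma with Benjamini-Hochberg adjustment) and -5.53 ± 0.12 without RPMI-1640 library 1. TXNIP fell to 36.7 ± 2.65 TPM in HPLM against 677 ± 328 TPM in RPMI-1640, a log2 change of -4.02 ± 0.42 and -4.52 ± 0.11 without that library. INSIG1 fell to 8.58 ± 1.35 TPM in HPLM against 150.0 ± 26.6 TPM in RPMI-1640 (-3.97 ± 0.20; -4.13 ± 0.14 without library 1), and STARD4 (ENSG00000164211, chromosome 5, 111496033 to 111512590), a cholesterol transfer protein, to 2.87 ± 0.160 TPM in HPLM against 41.4 ± 2.55 TPM in RPMI-1640 (-3.45 ± 0.14; -3.42 ± 0.11 without library 1). RARRES1 (ENSG00000118849, chromosome 3, 158696892 to 158732696), a gene induced by retinoids, rose to 39.5 ± 1.22 TPM in HPLM against 3.79 ± 0.991 TPM in RPMI-1640 (3.10 ± 0.19; 3.26 ± 0.10 without library 1).

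NRF2 targets and glutathione genes fell in 16 of 23 cases (20 adjusted over the list alone) and 22 without library 1, with medians of -1.41 and -1.38 (camera adjusted p = 2.17e-14 and 5.80e-13, and adjusted p = 0.580 and 0.988 with an estimated correlation). AKR1C1 and AKR1C2 changed by -3.93 ± 0.63 and -4.77 ± 0.75 with all libraries and by -4.71 and -5.70 without library 1, and the malic enzyme gene ME1 by -1.86 ± 0.16 and -1.78. Cholesterol synthesis and SREBP2 genes fell in 11 of 24 cases (14 adjusted over the list alone) and 20 without library 1, with medians of -1.25 and -0.87 (camera adjusted p = 7.00e-12 and 4.69e-09, and adjusted p = 0.580 and 0.988 with an estimated correlation). HMGCS1 changed by -2.09 ± 0.44 and -1.56. Fatty acid synthesis genes fell in 5 of 16 cases (8 adjusted over the list alone) and 12 without library 1, with medians of -0.84 and -0.64 (camera adjusted p = 3.50e-06 and 1.30e-04, and adjusted p = 0.580 and 0.988 with an estimated correlation). SCD changed by -2.23 ± 0.15 and -2.17. Among 7 glucose-sensing genes 3 fell, the same number adjusted over the list alone, and 4 without library 1, with medians of -1.69 and -2.02 (camera adjusted p = 0.00894 and 0.00721, and adjusted p = 0.580 and 0.988 with an estimated correlation). ARRDC4 changed by -4.18 ± 0.24 and -4.41. Glycolysis and glucose uptake genes fell in 5 of 23 cases (11 adjusted over the list alone) and 13 without library 1, with medians of -0.73 and -0.63 (camera adjusted p = 1.00e-05 and 0.00102, and adjusted p = 0.580 and 0.988 with an estimated correlation). Aldolase C, ALDOC, changed by -2.44 ± 0.34 and -2.83, and PFKFB3, a regulator of glycolytic flux, by -1.32 ± 0.15 and -1.24.

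Cell cycle and DNA replication genes fell in 13 of 28 cases (15 adjusted over the list alone), with a median of -1.46 (camera adjusted p = 1.36e-08, and adjusted p = 0.583 with an estimated correlation). Without library 1, 15 fell and 7 rose, with a median of -0.95 (adjusted p = 0.0336, and adjusted p = 0.988 with an estimated correlation). The mitotic genes AURKA, a kinase, and CCNB1, cyclin B1, changed by -2.10 ± 0.16 and -1.84 ± 0.14 with all libraries and by -2.01 and -1.79 without library 1. Cytosolic ribosomal protein genes were called up by camera (median 0.49, adjusted p = 2.95e-08, and adjusted p = 0.583 with an estimated correlation) with 0 of 25 genes past the limma threshold, also 0 adjusted over the list alone, 12 raised at an unadjusted p under 0.05, 2 raised by edgeR and 11 in the authors' deposited table. Without library 1, 12 rose (median 0.34, adjusted p = 2.15e-04, and adjusted p = 0.988 with an estimated correlation). RPLP0 was at 0.74 ± 0.17 and then 0.63, and RPS9 at 0.60 ± 0.15 and 0.54. Mitochondrially encoded mRNAs were likewise called up (median 0.40, adjusted p = 0.00204, and adjusted p = 0.628 with an estimated correlation) with 0 of 13 past the limma threshold, also 0 adjusted over the list alone, 5 raised at an unadjusted p under 0.05, 0 by edgeR and 1 in the authors' deposited table. The call was lost without library 1 (median 0.31, adjusted p = 0.0811), where 3 rose. MT-CYB was at 0.96 ± 0.32 and MT-ND2 at 0.95 ± 0.26 with all libraries, and without library 1 both rose, by 0.62 and 0.69.

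The amino acid response in HT29 depended on RPMI-1640 library 1. With all libraries 0 of 32 ATF4 targets rose and 1 fell by limma, the same numbers adjusted over the list alone. By other counts 0 rose and 6 fell at an unadjusted p under 0.05, 0 and 1 by edgeR, and 0 and 6 in the authors' deposited table. The median was -0.22 (camera adjusted p = 0.239). Without library 1, 25 of 33 fell and 1 rose, 27 and 1 adjusted over the list alone, with a median of -0.67 (adjusted p = 4.69e-09, and adjusted p = 0.988 with an estimated correlation). DDIT4 stood at 16.6, 358 and 355 TPM in RPMI-1640 libraries 1, 2 and 3 and at 43.2 ± 5.35 TPM in HPLM, and CHAC1 at 4.86, 93.4 and 94.7 against 33.4 ± 2.56 TPM. With all libraries the log2 changes were -0.15 ± 0.86 for ASNS, -0.13 ± 1.06 for CHAC1, -1.57 ± 1.15 for DDIT4, 0.36 ± 0.70 for TRIB3, -0.37 ± 0.41 for PSAT1, -0.05 ± 0.46 for PHGDH, -0.21 ± 0.24 for SLC7A5, -0.88 ± 0.22 for SLC7A11 and -0.73 ± 0.69 for ASS1, none past the threshold by limma (adjusted p at least 0.0677). Without library 1 all fell, with log2 changes in that order of -1.23, -1.47, -3.02, -0.51, -0.86, -0.61, -0.45, -1.07 and -1.59 (adjusted p at most 0.0349). The sign of the PHGDH change also turned under trimmed mean scaling (0.04), and those of ASNS and CHAC1 on leaving out mitochondrially encoded genes. ALDH18A1 fell in both (-0.98 ± 0.16 and -1.06). MAT2A did not pass in either (0.17 ± 0.21, adjusted p = 0.663; 0.05, adjusted p = 0.846). Of 23 aminoacyl-tRNA synthetase genes 1 fell, 0 adjusted over the list alone, and the list was not called (median -0.08, 0.02 after trimmed mean scaling; camera adjusted p = 0.579). Without library 1, 5 fell and 2 rose, and it was again not called (median -0.05, adjusted p = 0.667). EEF1E1, a scaffold of the synthetase complex, was the one that fell with all libraries (-0.88 ± 0.19 and -0.76 without library 1), and HARS1, for histidine, was at -0.38 ± 0.19 (adjusted p = 0.289) and -0.20 (adjusted p = 0.161). Plasma membrane amino acid transporters were called down (median -0.40, camera adjusted p = 0.0222, and adjusted p = 0.580 with an estimated correlation) with 1 of 21 lowered, 4 lowered and 1 raised adjusted over the list alone. Without library 1, 13 were lowered and 4 raised (median -0.44, adjusted p = 0.0336, and adjusted p = 0.988 with an estimated correlation). SLC6A6 fell, with a log2 change of -1.65 (-1.67 without library 1), and SLC3A1, of the cystine and dibasic amino acid carrier, was at -0.85 ± 0.20 (adjusted p = 0.0596) and -1.02.

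Unfolded protein response genes were called down in HT29 (median -0.31, camera adjusted p = 0.0189, and adjusted p = 0.580 with an estimated correlation), with 1 of 20 lowered, 2 adjusted over the list alone, and 9 without library 1 (median -0.35, adjusted p = 0.00364, and adjusted p = 0.988 with an estimated correlation). The chaperone gene HSP90B1 changed by -0.89 ± 0.17 and -1.01, and MANF, a secreted stress factor, by -0.64 ± 0.14 (adjusted p = 0.0537) and -0.69 (adjusted p = 0.00540). Heat shock genes fell in 4 of 14 cases, the same number adjusted over the list alone (median -0.61, camera adjusted p = 0.0189, and adjusted p = 0.583 with an estimated correlation), and the call was lost without library 1 (median -0.12, adjusted p = 0.409), where 4 fell and 2 rose. HSPA1A changed by -1.08 ± 0.14 and -1.04, and HSPB1 by -1.11 ± 0.18 and -1.24. Hypoxia genes fell in 4 of 21 cases (11 lowered and 1 raised adjusted over the list alone). Without library 1, 18 of 22 fell and 1 rose, with medians with and without it of -0.81 and -1.09 (camera adjusted p = 7.81e-04 and 8.04e-08, and adjusted p = 0.628 and 0.988 with an estimated correlation). P4HA2, of collagen prolyl hydroxylation, changed by -1.11 ± 0.23 and -1.34, and ERO1A, an oxidase of the endoplasmic reticulum, by -0.81 ± 0.16 and -0.90. Immediate early genes were not called with all libraries (median 0.29, adjusted p = 0.127; 1 of 17 raised, the same number adjusted over the list alone) or without library 1 (median -0.28, adjusted p = 0.128; 3 raised and 8 lowered). KLF6, a zinc finger factor, rose by 0.96 ± 0.15 and 1.02, and DUSP6, a phosphatase of ERK, was at 0.47 ± 0.17 (adjusted p = 0.157) and 0.34 (adjusted p = 0.0480). Interferon response genes were not called (median 0.05, adjusted p = 0.579; 1 of 29 lowered, the same number adjusted over the list alone), while without library 1, 16 rose and 3 fell (median 0.44, adjusted p = 0.00102, and adjusted p = 0.988 with an estimated correlation). OASL, an antiviral protein gene, changed by -1.09 ± 0.15 and -1.16, and the signal transducer STAT2 by 0.71 ± 0.17 (adjusted p = 0.0670) and 0.85 (adjusted p = 0.00228).

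Colonic epithelial genes fell in 3 of 13 cases in HT29 (5 adjusted over the list alone; median -0.57, camera adjusted p = 0.0251, and adjusted p = 0.580 with an estimated correlation), and the call was lost without library 1 (median -0.69, adjusted p = 0.168), where 7 fell and 2 rose. The adhesion gene CDH17 changed by -1.24 ± 0.18 and -1.15, and GPA33, an intestinal surface antigen, by -1.42 ± 0.22 and -1.25, from 3.41 ± 0.527 and 2.65 ± 0.948 TPM in RPMI-1640. Of 7 lung epithelial genes 0 passed the limma threshold, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 by edgeR and 0 in the authors' deposited table (median -0.43, camera adjusted p = 0.396). Without library 1, 3 fell and 1 rose, and the list was not called (median -0.30, adjusted p = 0.253). AGER, a pattern receptor, was at -1.07 ± 0.59 (adjusted p = 0.320) and the protease gene NAPSA at -0.33 ± 0.17 (adjusted p = 0.294). Both passed without library 1, AGER at -1.79 (adjusted p = 3.71e-04) and NAPSA at -0.44 (adjusted p = 0.0436). Clathrin-mediated endocytosis genes were not called (median -0.16, adjusted p = 0.127), with 1 of 22 lowered and 0 raised, and 2 and 1 adjusted over the list alone. Without library 1, 6 of 23 fell and 2 rose (median -0.17, adjusted p = 0.461). The adaptor genes AP2A2 and DAB2 were at -0.72 ± 0.15 (adjusted p = 0.0454) and 0.64 ± 0.14 (adjusted p = 0.0509), and CLTC at -0.49 ± 0.29 (adjusted p = 0.357). Without library 1, AP2A2 was at -0.68 (adjusted p = 0.00819), DAB2 passed at 0.65 (adjusted p = 0.00610), and CLTC was at -0.18 (adjusted p = 0.354). Caveolae genes were not called either (median -0.17, mean 0.02, camera down, adjusted p = 0.724; median 0.02 without library 1, 3 raised and 3 lowered, adjusted p = 0.862), with 1 of 9 raised and 1 lowered, 1 and 2 adjusted over the list alone. CAVIN2 rose by 2.86 ± 0.17 and 2.97. PACSIN3, a membrane-shaping protein gene, changed by -1.33 ± 0.24 and -1.59, and CAV1, at 2.78 ± 0.0364 TPM in HPLM, by 0.19 ± 0.72 (adjusted p = 0.898) and 1.06 (adjusted p = 0.00937). The sign of the CAV1 change with all libraries was negative in the authors' deposited table.

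Other genes raised most in HT29 were VGLL1, a cofactor of TEAD factors (3.00 ± 0.27 and 3.25 without library 1), CLIC5, an intracellular chloride channel gene (2.69 ± 0.25 and 2.94), RGCC, a cell cycle regulator (2.56 ± 0.41 and 3.04), RAMP1, a receptor partner for CGRP (2.53 ± 0.23 and 2.62), GALNT5, of protein O-glycosylation (2.14 ± 0.35 and 2.54), and the lectin gene CLEC3A (2.04 ± 0.28 and 2.35). FRMD5, a FERM domain protein gene, rose by 2.04 ± 0.35 and 2.45, the trypsinogen gene PRSS2 by 2.40 ± 0.22 and 2.21, and the pseudogene IGFL1P1 by 2.73 ± 0.50 and 3.31. Among those lowered most were TFF1, a trefoil peptide of mucous cells (-3.19 ± 0.55 and -2.60), the aldehyde dehydrogenase gene ALDH3A1 (-2.94 ± 0.19 and -3.11) and ANXA13, an annexin of intestinal epithelium (-2.87 ± 0.47 and -2.30).

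With all libraries limma called 999 of 16352 genes in HT29, 414 raised and 585 lowered. After trimmed mean scaling the split was 850 and 682, after median centring 756 and 702, and without mitochondrially encoded genes 987 and 535. Without RPMI-1640 library 1 limma called 6767 of 17273 genes, 3074 raised and 3693 lowered, which included all 414 raised and 585 lowered genes called with it. Limma called 5 and 147 genes without RPMI-1640 library 2 or 3, and 0, 5 and 0 without HPLM library 1, 2 or 3, with 2607 to 3745 genes at an unadjusted p under 0.05 and 1 to 692 edgeR calls. The lists camera called numbered 16 of 42 with and 16 without library 1, 0 with an estimated correlation in each, and 11 by fry with all libraries. Other splits of the HT29 libraries also gave up to 16 lists.

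**Figure D2:**
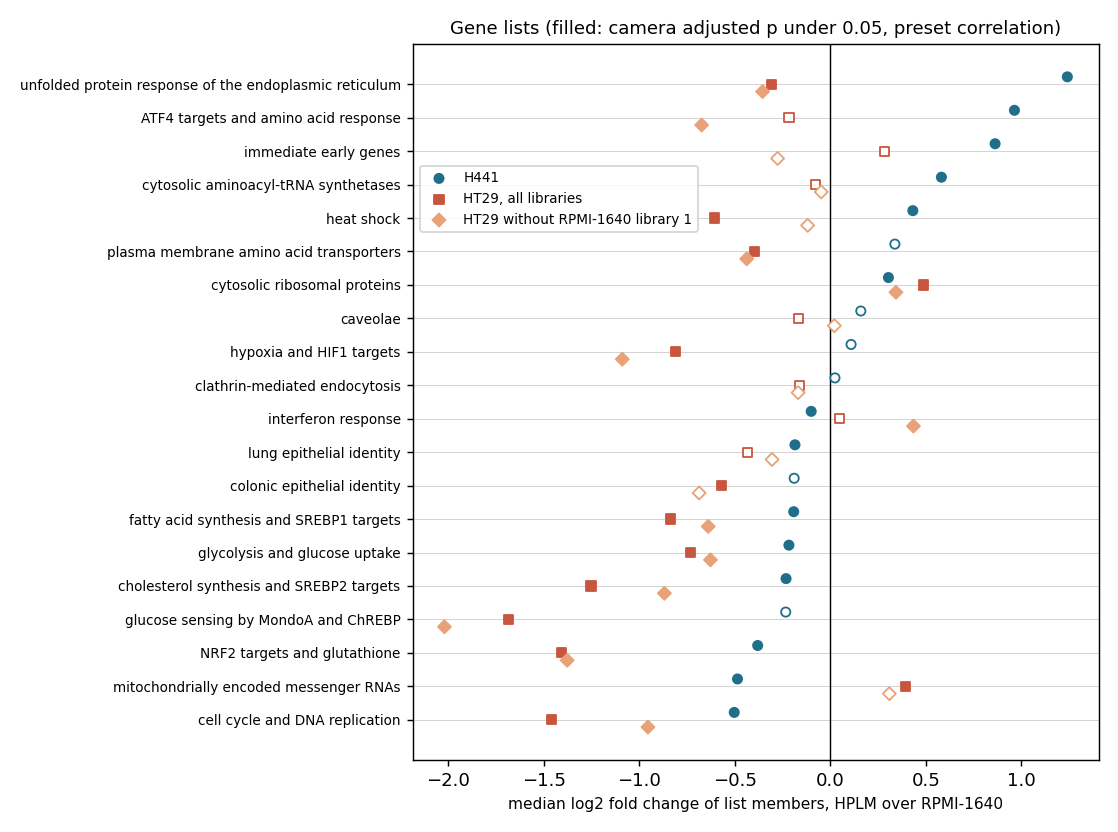
Median log2 fold change, HPLM over RPMI-1640, of the members of 20 gene lists in H441 (circles), HT29 (squares) and HT29 without RPMI-1640 library 1 (diamonds), filled where camera with the preset correlation gave an adjusted p under 0.05. The median of ATF4 targets was 0.96 in H441, -0.22 in HT29 and -0.67 in HT29 without that library.

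Whether the 2 lines responded differently was tested by the interaction term. Its errors pool the spread of both lines, so its p-values can be too small where the HT29 libraries spread more. HMOX1 rose in H441 and stood at 3.90 ± 0.523 TPM in HPLM against 14.8 ± 7.60 TPM in RPMI-1640 in HT29, a difference of -5.41 ± 0.46 (HT29 minus H441, adjusted p = 1.20e-04, limma with Benjamini-Hochberg adjustment). Its HT29 change without library 1 was -2.03 (adjusted p = 5.52e-04). AKR1B10 fell in both lines, in H441 with a log2 change of -0.65, and more in HT29 (-4.60 ± 0.33, adjusted p = 5.80e-05). The H441 call of AKR1B10 was lost without RPMI-1640 library 1 (-0.68), HPLM library 1 (-0.56) or HPLM library 3 (-0.64). HSPA1A moved in opposite directions (-3.89 ± 0.15), as did NMRAL2P, a pseudogene that rose in H441 (0.94 ± 0.05) and fell in HT29 (-2.71 ± 0.54, and -3.37 without library 1; difference -3.65 ± 0.60). STARD4 fell in HT29 and was at 0.01 ± 0.06 in H441, where it passed as lowered after trimmed mean scaling (-0.13, adjusted p = 0.0324) and by edgeR (-0.14, adjusted p = 0.0322), a difference of -3.45 ± 0.12 (adjusted p = 9.11e-07). In the other direction VGLL1 rose in HT29 and was at 0.05 ± 0.12 in H441, where its sign turns under other scalings (-0.09 after trimmed mean scaling), a difference of 2.95 ± 0.31 (adjusted p = 3.62e-04). RGCC, RAMP1 and GALNT5 rose in HT29 and fell in H441, with log2 changes there of -0.55, -0.20 and -0.34, with differences of 3.12 ± 0.46, 2.73 ± 0.25 and 2.48 ± 0.39. The H441 call of RAMP1 was lost on leaving out any 1 of the 6 libraries (-0.23 to -0.15, adjusted p = 0.0646 to 0.125). IGLV2-14, an immunoglobulin segment, differed by 4.37 ± 1.30 (adjusted p = 0.0483) and passed in neither line alone (-1.88 ± 0.98 and 2.49 ± 0.72), nor in HT29 without library 1 (2.24, adjusted p = 0.0685). It passed in H441 without HPLM library 1 (-3.02, adjusted p = 0.00331). In H441 in HPLM it stood at 9.77, 0 and 0 TPM in libraries 1, 2 and 3.

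ATF4 targets differed by a median of -1.21, with 14 of 33 members lower in HT29 (19 adjusted over the list alone; camera adjusted p = 1.80e-05, and adjusted p = 0.700 with an estimated correlation), and 33 of 34 without HT29 RPMI-1640 library 1 (median -1.61). Unfolded protein response genes differed by -1.48, 15 of 20 lower in HT29 (17 adjusted over the list alone; adjusted p = 3.14e-11, and adjusted p = 0.138 with an estimated correlation), and heat shock genes by -1.03, 8 of 14 lower (9 adjusted over the list alone; adjusted p = 8.22e-06, and adjusted p = 0.450 with an estimated correlation). Without library 1 the medians of these lists were -1.57, with 18 of 20 lower, and -0.90, with 10 of 14 lower and 1 higher. Mitochondrially encoded mRNAs were higher in 9 of 13 cases (12 adjusted over the list alone; median 1.03, adjusted p = 1.04e-10, and adjusted p = 0.450 with an estimated correlation), and in 11 without library 1 (median 0.88). Cell cycle genes were lower in 13 of 28 cases (14 adjusted over the list alone; median -0.97, adjusted p = 0.00181, and adjusted p = 0.700 with an estimated correlation). Without library 1, 12 cell cycle genes were higher and 14 lower, the list was not called (adjusted p = 0.980), and its median of -0.52 and mean of -0.21 lay below 0 while the camera direction was up. TXNIP, past the threshold in both lines, did not differ detectably (0.55 ± 0.47, adjusted p = 0.481). With library 1, neither ASNS (-1.45 ± 0.96, adjusted p = 0.361) nor DDIT4 (-2.54 ± 1.29, adjusted p = 0.225) passed. Without it both did, ASNS at -2.53 ± 0.11 (adjusted p = 1.07e-06) and DDIT4 at -3.99 ± 0.14 (adjusted p = 3.40e-07).

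The test called 2831 of 18703 genes, 583 higher and 2248 lower in HT29. Of these calls, 667 were of genes under the TPM filter in 1 of the lines. Among genes tested in both lines 332 were higher and 1832 lower. The split was 1137 and 1531 after trimmed mean scaling and 1234 and 1197 without mitochondrially encoded genes, and without HT29 RPMI-1640 library 1 it was 1964 and 5118. The total was 1865 without H441 RPMI-1640 library 1, 1822 without its library 3, 1862 and 1839 without H441 HPLM library 1 or 3, and 1793 without HT29 HPLM library 3. Among 14107 genes tested in both lines, 233 were lowered in both, against 56.2 for independent lists (two-sided Fisher's exact test, p = 1.78e-92), and 128 raised in both, against 105 (p = 0.00594). Fisher's test takes genes as independent draws, which they are not, so these p-values can be too small. Genes raised in H441 and lowered in HT29 numbered 67, against 173, and the reverse 16, against 34.2. Without library 1 the shared counts were 755 lowered, against 343, and 1192 raised, against 882. The opposite directions numbered 734, against 1044, and 142, against 289. The odds ratio of the lowered overlap was 7.96 with and 3.98 without library 1, and that of the raised overlap 1.39 and 1.87. After trimmed mean scaling, with all libraries, the odds ratios were 5.61 for the lowered and 2.16 for the raised overlap. Across genes, which are not independent replicates, the log2 fold changes of the 2 lines had a Pearson correlation of 0.280 and a Spearman correlation of 0.285.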

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

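Both tests of explanations for the difference in ATF4 targets, and the count of other splits, were chosen after the result was seen. HMOX1, the inducible heme oxygenase, had the lowest difference of the named genes. The interaction term (HT29 minus H441, log2) passed in 2831 of 18703 genes, and in 73 of the 108 named genes, many of which were chosen for large changes. Of stress response genes those that passed were lower in HT29: HMOX1 -5.41, HSPA1A -3.89, HSPA1B -3.26, HSPA6 -3.03, ATF3 -2.99, DDIT3 -2.49, DNAJB9 -3.30. Others of endoplasmic reticulum and heat stress were HERPUD1 -2.46, MANF -1.83, HSP90B1 -1.68, ERO1A -0.93, HSPB1 -0.76. Aldo-keto reductases and other NRF2-related genes that passed were AKR1B10 -4.60, AKR1C2 -3.36, NMRAL2P -3.65, ALDH3A1 -2.63, ME1 -1.72. Sterol and lipid genes were STARD4 -3.45, INSIG1 -2.19, HMGCS1 -1.86, SCD -0.49. Transporters and amino acid genes were SLC16A1 -2.72, SLC1A4 -2.17, SLC7A11 -1.63, SLC7A5 -0.93, SLC3A1 -0.92, SLC6A6 -0.59, ALDH18A1 -0.74, TARS1 -1.02, EEF1E1 -0.91. Genes of sugar metabolism, glucose sensing and collagen hydroxylation were ALDOC -2.13, HK2 -1.78, PFKFB3 -1.56, ARRDC4 -1.36, P4HA2 -1.16. The mitotic genes were AURKA -1.39, CCNB1 -1.30. Secreted and surface genes were TFF1 -3.49, MMP9 -2.88, HBEGF -2.80, GPA33 -1.43, CDH17 -1.36. The annexin gene ANXA13 was at -2.98 and SPRR2D, of the cornified envelope, at -2.78. Endocytic and antiviral genes were SNX9 -1.37, PACSIN3 -1.35, AP2A2 -0.86, PICALM -0.64, IRF1 -1.07, OASL -0.99.

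In the other direction RGCC, RARRES1 and VGLL1 were higher in HT29 by the interaction term: RGCC 3.12, RARRES1 3.15, VGLL1 2.95, IGFL1P1 2.96, FRG2EP 2.77, RAMP1 2.73, CLIC5 2.58. Further genes were GALNT5 2.48, CLDN8 2.32, ANKRD36C 2.20, RNASE1 2.08, CLEC3A 1.90, CAVIN2 1.78, FRMD5 1.45, PRSS2 1.24. Mitochondrially encoded genes were MT-ND2 1.31, MT-CYB 1.38, MT-ND5 1.19, MT-ND6 1.07. The rest were KLF6 0.70, DAB2 0.65, STAT2 0.77, IGLV2-14 4.37. Of the genes above, 13 lay under the TPM filter in the other line, so that their value mostly restates the change of 1 line. These were SPRR2D, MMP9, FRG2EP and CLDN8, which changed in H441, and CDH17, ANXA13, ALDH3A1, CLIC5, RARRES1, SLC3A1, DAB2, TFF1 and IGFL1P1 in HT29. The value of CLDN8 equals its H441 change with the sign reversed. The median difference of all genes tested was -0.21. Of the described lists, 13 differed by camera with the preset correlation and 0 with an estimated correlation. Their median differences were -1.48 for the unfolded protein response, -1.21 for ATF4 targets, -1.17 for cholesterol synthesis, -1.03 for heat shock and -0.97 for the cell cycle. They were -0.96 for NRF2 targets, -0.73 for amino acid transporters, -0.71 for hypoxia, -0.64 for glycolysis, -0.58 for tRNA synthetases and -0.56 for fatty acid synthesis. Those above 0 were 1.03 for mitochondrially encoded mRNAs and 0.19 for ribosomal proteins, where limma called 0 of 25 single genes and 2 were higher at an unadjusted p under 0.05. Without HT29 RPMI-1640 library 1, the calls were lost for fatty acid synthesis (median -0.33, adjusted p = 0.0904), ribosomal proteins (0.07, adjusted p = 0.103) and the cell cycle (-0.52, adjusted p = 0.980). Calls were gained for immediate early genes (-1.36, adjusted p = 6.62e-07), interferon response genes (0.57, adjusted p = 5.59e-07) and glucose sensing (-0.42, adjusted p = 0.0331), each with an adjusted p = 0.567 with an estimated correlation.

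The other 35 named genes did not pass with all libraries (adjusted p at least 0.0503). Many of these misses rest on HT29 RPMI-1640 library 1: without it 25 of them passed. Those still not past the threshold were MKI67, CAV1, CLTC, NAPSA, FDFT1, RPL3, RPS9, PPFIA4, MAT2A and TXNIP. Of the genes that passed with it, 1 did not without it, IGLV2-14 (4.12 ± 1.45, adjusted p = 0.0517). Of stress and amino acid genes the 35 included, with values without library 1 in brackets, DDIT4 -2.54 (-3.99), CHAC1 -1.81 (-3.15), PPP1R15A -1.69 (-2.28), TRIB3 -1.48 (-2.35), ASNS -1.45 (-2.53), PSAT1 -1.29 (-1.78), AARS1 -1.16 (-1.66), ASS1 -0.59 (-1.46), HARS1 -0.50 (-0.32), PHGDH -0.03 (-0.59), MAT2A 0.44 (0.32). Of NRF2, lipid and sugar genes they were AKR1C1 -1.64 (-2.42), AKR1C3 -0.13 (-0.51), ACSS2 -0.61 (-1.08), FDFT1 -0.13 (0.15), TXNIP 0.55 (0.05). Early response, hypoxia and cell cycle genes among them were EGR1 -2.19 (-3.51), MYC -1.80 (-1.05), DUSP6 -0.16 (-0.29), VEGFA -0.88 (-1.87), PPFIA4 0.26 (0.03), CCNA2 -1.67 (-1.12), MKI67 -0.69 (-0.21). The rest were CEACAM5 -0.44 (-1.11), CEACAM6 0.47 (0.54), SFTPA1 1.09 (1.39), SFTPA2 1.26 (1.66), AGER -0.55 (-1.28), NAPSA -0.28 (-0.38), OAS1 0.82 (1.25), CAV1 -0.43 (0.44), CLTC -0.31 (0.00), RPL3 -0.04 (-0.11), RPLP0 0.48 (0.37), RPS9 0.21 (0.15). In HPLM, SFTPA1 and SFTPA2 stood at 0.737 ± 0.404 and 1.05 ± 0.397 TPM in HT29, and AKR1C1 at 0.714 ± 0.113 TPM in H441. At such levels the pseudocount shrinks the log2 change, so the size of these differences is uncertain.

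The count of genes whose response differed, 2831, was reached by 1 of 100 splits drawn, the real one included, and the highest of the others gave 2375. Most drawn splits also break up the H441 grouping and with it the H441 response, so they do not isolate the difference between the lines. Splits that keep the real H441 grouping number 20, the real one included, too few for a share under 0.05. Of the others drawn, 8 kept it, among them the 4 highest.

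ATF4 targets rose in H441 and not in HT29, with a median difference of -1.21. Scaling of TPM as the whole cause is argued against, since after trimmed mean scaling the median difference was -1.01, with 29 of 32 members below 0 (SD of members 0.79). HT29 RPMI-1640 library 1 as the whole cause could not be tested by leaving it out. ATF4 targets were lower in it than in libraries 2 and 3 (median log2 -1.46), so the omission was bound to lower the median difference. Without it the median was -1.61, with 31 of 32 members below 0 (SD of members 1.10). Of 12 ATF4 targets 2-fold apart between the media, 11 lay nearer to HPLM in library 1. The direction in HT29 thus rests on which RPMI-1640 libraries are typical, which stays open. A different response of lung and colorectal lines to the medium stays open and untested, because only 1 line of each tissue was used. Whether libraries of 1 group were made or sequenced together is not given in the sources used here.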

How the results depend on the processing

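The tests by edgeR, with array weights, over the genes of the authors' table, and those of the difference, lists and overlap under other scalings were chosen after the results were seen. Of 188 results under trimmed mean scaling, 176 kept their direction and side of the threshold, 6 lost the call, 5 gained one and 1 reversed. The same count was 133 of 144 without mitochondrially encoded genes, 130 of 138 by edgeR, 127 of 138 in the authors' table and 122 of 138 with array weights. It was 180 of 188 with a pseudocount of 0.1, 136 of 138 with 0.5, 172 of 181 with a TPM filter of 5, 124 of 138 with none and 135 of 138 with an intensity trend. Median centring ended 1 call, gave 8 others and reversed 1 result. A replicate block kept 93 of 138, and leaving out HT29 RPMI-1640 library 1 kept 71 of 99. Leaving out HT29 HPLM library 1, 2 or 3 kept 35, 39 and 35 of 79, and most of the rest lost the call. Without HT29 RPMI-1640 library 2 or 3 the counts were 40 and 54 of 79. Leaving out any H441 library kept 75 or 76 of 79. Camera with an estimated correlation kept 13 of 40.

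In H441 the total of 7404 genes became 4307 at an adjusted p under 0.01 and 590 with a 2-fold minimum, both by construction. The 5546 raised genes became 3208 after median centring, 3662 in the authors' table, 3334 at 0.01 and 482 at 2-fold. The 1858 lowered genes became 3355 without mitochondrially encoded genes, 4171 after median centring and 3497 after trimmed mean scaling, as each lowers fold changes by nearly the same amount. They were 3775 in the authors' table, 4190 by edgeR, 973 at 0.01 and 108 at 2-fold. Leaving out 1 library gave totals of 5368 to 6421, 4135 to 4985 raised and 1233 to 1666 lowered, lowest without RPMI-1640 library 1. The authors' own 7437 genes became 778 at 2-fold. STARD4, at 0.01, reversed to -0.13 without mitochondrially encoded genes, -0.18 after median centring, -0.13 after trimmed mean scaling and -0.14 by edgeR.

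In HT29 the total of 999 became 1522 without mitochondrially encoded genes, 1532 after trimmed mean scaling, 3416 in the authors' table, 1776 by edgeR, 4625 with array weights and 9916 by edgeR without RPMI-1640 library 1. It was 42 at 0.01 and 623 at 2-fold. With a replicate block limma called 0 genes (0 raised and 0 lowered), with 3611 at an unadjusted p under 0.05. edgeR was not run with a block. Whether the library numbers pair the media is not given in the sources used here. In HT29, deviations of equal numbers correlated by -0.0973 to 0.171 and those of unequal numbers by -0.167 to 0.123. With 3 libraries per medium, such weak correlations neither show nor exclude a pairing. The 414 raised genes became 987, 756 and 850 without mitochondrially encoded genes, after median centring and after trimmed mean scaling. They were 1490 in the authors' table, 841 by edgeR, 2261 with array weights, 4930 by edgeR without library 1, 13 at 0.01 and 256 at 2-fold. The 585 lowered genes became 1926, 935, 2364, 4986, 29 and 367 in the same order. Leaving out 1 library gave totals of 0 to 6767, 0 to 3074 raised and 0 to 3693 lowered, highest without RPMI-1640 library 1. The authors' 3416 genes became 2197 at 0.01 and 1420 at 2-fold. TRIB3, at 0.36, reversed to -0.51 without library 1 by limma and -0.49 by edgeR. Its range on leaving out 1 library was -0.51 to 0.79.

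The 2831 genes that differed between lines became 1159 at 0.01, and 1793 to 7082 on leaving out 1 library, lowest without HT29 HPLM library 3 and highest without HT29 RPMI-1640 library 1. Those higher in HT29, 583, became 1137 after trimmed mean scaling, 1234 without mitochondrially encoded genes, 215 at 0.01 and 377 to 1964 on leaving out 1 library. Those lower, 2248, became 1197 without mitochondrially encoded genes, 944 at 0.01 and 1387 to 5118. A z test on the authors' fold changes, with errors computed back from their p-values, gave 2376. Genes raised in both lines, 128, became 2 at 0.01, 13 at 2-fold, 1192 without HT29 RPMI-1640 library 1, 261 after trimmed mean scaling and 477 in the authors' tables. Genes lowered in both, 233, became 15, 18, 755, 352 and 887. The lists camera called, 19 in H441 and 16 in HT29, numbered 0 and 0 with an estimated correlation, and 30 by fry in H441. Except where construction is named, the cause was not tested. HT29 RPMI-1640 library 1 had the fewest recovered reads, 14151527, and whether depth limits any result was not tested.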

Other observations

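The tests of distance from HPLM, of the media axis in other libraries and by list, of H441 RNA, of mitochondrial share and of RNA per cell, the count of other splits, and the lists without HT29 RPMI-1640 library 1, were chosen after the results were seen. Beyond the described lists, inflammatory cytokine genes rose in H441 (13 of 18 raised and 1 lowered, 14 and 1 adjusted over the list alone, median 0.64, camera adjusted p = 7.25e-04, and adjusted p = 0.593 with an estimated correlation). The chemokine CXCL2 rose by 1.63, IL6 by 1.63, the cyclooxygenase PTGS2 by 1.38 and the siderophore-binding LCN2 by 1.35. MYC targets and ribosome biogenesis genes rose in 17 of 20 cases (17 adjusted over the list alone, median 0.42, adjusted p = 9.32e-05, and adjusted p = 0.593 with an estimated correlation). Lipoprotein and nanoparticle surface receptor genes fell in 5 and rose in 2 of 15 cases (5 and 2 adjusted over the list alone, median -0.10, adjusted p = 0.00421, and adjusted p = 0.684 with an estimated correlation). LRP8, a receptor of apolipoprotein E, changed by -0.80, the scavenger receptor SCARB1 by -0.29, and LRP6, of Wnt signalling, by 0.68. Genes of gluconeogenesis, lactate and the TCA cycle (median -0.07, adjusted p = 0.00820, and adjusted p = 0.708 with an estimated correlation) and of the nuclear encoded respiratory chain (median -0.01, adjusted p = 0.0160, and adjusted p = 0.813 with an estimated correlation) were called down.

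In HT29 the same receptor list was not called (median -0.50, adjusted p = 0.199), with 2 of 15 lowered (2 adjusted over the list alone), among them LRP10, of protein sorting (-0.82). Without library 1, 6 fell and 2 rose, and it was again not called (median -0.28, adjusted p = 0.239). Inflammatory cytokine genes were called up (median 0.52, adjusted p = 0.0430, and adjusted p = 0.580 with an estimated correlation), where the chemokine CXCL3 (0.93) and serum amyloid SAA1 were the 2 members that rose. Without library 1, 9 rose and 4 fell (median 0.57, adjusted p = 0.0461, and adjusted p = 0.988 with an estimated correlation). Arginine and proline genes were called down (median -0.43, adjusted p = 0.0232, and adjusted p = 0.580 with an estimated correlation), with the creatine kinase CKB at -1.34. The call was lost without library 1 (median -0.40, adjusted p = 0.0663). Gluconeogenesis, lactate and TCA cycle genes were called down too (median -0.53, adjusted p = 0.00103, and adjusted p = 0.628 with an estimated correlation), as they were without library 1 (median -0.27, adjusted p = 0.0336, and adjusted p = 0.988 with an estimated correlation). Without RPMI-1640 library 1, purine and pyrimidine synthesis was called up (median 0.31, adjusted p = 0.0435, and adjusted p = 0.988 with an estimated correlation) and p53 targets down (median -0.40, adjusted p = 0.00642, and adjusted p = 0.988 with an estimated correlation). Between the lines arginine genes (median difference -0.59, adjusted p = 0.0273), MYC targets (-0.54, adjusted p = 0.0273) and epithelial to mesenchymal transition genes (-0.35, adjusted p = 0.0301) were lower in HT29. These had adjusted p = 0.450, 0.781 and 0.450 with an estimated correlation. The median difference of all genes tested was -0.21, and -0.14 without library 1. Without library 1 the calls of arginine genes (-0.46, adjusted p = 0.0844) and MYC targets (-0.30, adjusted p = 0.179) were lost and that of epithelial to mesenchymal transition genes was not (-0.32, adjusted p = 0.0358, and adjusted p = 0.991 with an estimated correlation).

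HT29 RPMI-1640 library 1 differed from libraries 2 and 3 in named groups of genes. ATF4 targets were lower in it by a median log2 of -1.46, immediate early genes by -1.79 and hypoxia genes by -0.81. Cell cycle genes were higher by 1.61, purine and pyrimidine synthesis by 1.48, interferon response genes by 1.37 and heat shock genes by 1.03. In all, 2322 genes were 2-fold higher and 2018 lower, of 16002, against 323 apart between libraries 2 and 3.

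A wrong label, in the form of an HPLM library like the others placed among those of RPMI-1640, is argued against. In library 1, 3761 genes were 2-fold or more from the mean of the HPLM libraries, against at most 310 for an HPLM library. Library 1 was also far from RPMI-1640 libraries 2 and 3, with 2322 genes 2-fold higher and 2018 lower. Its distance therefore does not tell which medium it had, and an unusual HPLM library stays open. Of 132 genes 4-fold apart between the media, 42.4% lay nearer to RPMI-1640 in it. This met a bound of under 50%, written before the result, that was set for a wrong label. The bound was too loose, since in an HPLM library at most 4.44% lay nearer to RPMI-1640. In RPMI-1640 library 2 or 3 at least 92.8% did, so library 1 lay between the media. Of genes 2-fold apart, 10 of 10 cholesterol and 13 of 13 cell cycle genes lay nearer to RPMI-1640 in library 1. Nearer to HPLM were 11 of 12 ATF4 targets and 11 of 11 hypoxia genes. A library from outside the series was not tested. RNA of H441 cells is argued against by genes abundant in H441, which reached a median of 0.511% of their H441 level where 64.1% would be needed. A trend with transcript length or GC content explained 9.65% of the variance and left 3803 of 4297 genes 2-fold apart.

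For that library no biological explanation was tested, and culture density is not given in the sources used here.

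Calls in H441 were mostly raised, 74.9% of them. With mitochondrially encoded genes left out before scaling 54.4% were raised, so the lower mitochondrial share in HPLM may account for the surplus. Whether transcripts rose in number per cell cannot be told apart from this, since the 51.1% raised by edgeR is relative and no count of RNA per cell was made.

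The 6 libraries of a line make 10 splits, the real one included, too few for a share under 0.05. In H441 the real split gave 7404 genes and the highest other 11, and 1 split reached the real count, itself. For gene lists it was 19 and 11, and again 1 split. In HT29 the real split gave 999 genes by limma, reached by 1 split, and the highest other 0. For gene lists it was 16 and 16, and 5 splits gave as many, the real one included. The number of lists camera called in HT29 therefore does not set the media apart from other groupings of these libraries.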
